A study of Homo sapiens with 15 samples.

How the data were processed

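The samples were tumours grown from MCF-7, an oestrogen receptor positive human breast cancer cell line, here carrying a firefly luciferase reporter. Per the labels' protocols, the cells were cultured with 10% fetal bovine serum and injected either by the intra-iliac route, which gave bone lesions (8 libraries), or into the mammary fat pad, which gave orthotopic tumours (7 libraries). Total RNA was extracted with a column kit, and cDNA was made from at least 200 ng of it with SuperScript III reverse transcriptase and a second-strand synthesis module. Libraries were built from 1 ng of double-stranded DNA with Nextera XT, a tagmentation kit that does not mark the strand of the RNA. How the first strand was primed, and whether ribosomal RNA was removed, is not given in the sources used here.

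The authors deposited 1 table of expected counts, which are estimated read counts per gene that need not be whole numbers, for 58037 human genes with Ensembl identifiers. Per the submitters' processing notes, bcl2fastq 2.17, STAR, RSEM 1.2.28 and DESeq2 were used, and the builds GRCh38 and GRCm38 were named. The role of each build, the annotation release, the strand setting and the way in which reads of the mouse host were set apart are not given in the sources used here. RSEM divides reads that align to several genes among them by estimation, so values of genes with near-identical copies are uncertain. This holds for ACTG1, RN7SK, the class I HLA genes, the ribosomal protein genes and the histone genes, and for genes that overlap, such as MT-ATP8. Reads of a gene and of its antisense partner cannot be told apart in libraries without strand. Each of the 15 columns was matched to 1 sample by its name, and 0 columns were left unused.

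Gene symbols came from a table of Ensembl identifiers and symbols, which named 41640 of the 58037 genes, and 45 copies on the Y pseudoautosomal region were left unnamed. Positions came from GENCODE 29 on GRCh38, which held 57388 of the identifiers. Coordinates are 1-based.

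Expected counts were rounded to whole numbers. Genes were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the default filterByExpr filter by group and Benjamini-Hochberg adjustment at 0.05. The filter kept genes above 34.8 CPM (counts scaled to a common library size) in at least 7 libraries, and 6292 genes passed. This high limit follows from the low depth of the libraries. Log2 fold changes and folds are those fitted by edgeR, with a prior count and libraries weighted by depth, so they can differ from ratios of mean CPM. They are bone lesion over orthotopic tumour, and levels are CPM on the TMM scale, given as mean ± SD. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

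Gene lists of tumour cell programmes, RNA composition and host cell types, 44 in all, were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Only lists with at least 5 tested members entered, which left 27, and their p-values were adjusted over those 27. Each list was also tested with a correlation estimated from the data, and with fry, a rotation test of whether a list's genes move one way on balance. Neither fry p compares a list with other genes. Measures per library were compared by exact two-sided permutation tests over all 6435 assignments of the libraries to the groups.

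Total counts per library ran from 6601 to 1499869, and 4 bone lesion libraries held under 100000 counts. Confidence intervals of shares of counts are 95% Wilson intervals, and a count of 0 was taken to allow up to 3 counts. Both cover counting error only, since the reads carry no molecular identifiers. Intervals of the log2 fold change of a single gene come from the SE of the edgeR fit, and those of list medians from a bootstrap over list members.

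The genes, lists, tests and alternatives were fixed before the data were examined. Named genes were 11 genes fixed by name, and the 12 largest rises and 12 largest falls among genes past the adjusted threshold. A large change counted only with at least 5 CPM in the higher group and at least 80% of its libraries above the median of the other group, with a count of 0 taken as 0. For each list described, up to 4 members past the threshold were added, or the 2 most abundant members where none was past it.

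On counts simulated from these libraries, edgeR recovered 42 of 100 genes changed 2-fold and 96 of 100 changed 4-fold, and called 5 of 6092 unchanged genes. The simulation held no sets of libraries within a group and no variation shared between genes. It therefore gives no rate of false calls for the real libraries, where another split into 8 and 7 called 297 genes. Camera called 10 of 10 lists raised 1.5-fold and 0 of 10 unchanged lists, both with the preset and with the estimated correlation, although simulated genes vary independently and real genes do not. Fry called 0 of 10 raised lists at this depth, so a list missed by fry tells little.

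Replicates of a group were compared by a chi-square test of their counts. The closest pair, orthotopic tumours 1 and 2, had a chi-square of 1.43 per gene over 11147 genes, above the value of 1 that counting noise gives, and no libraries were merged. A value above 1 does not show separate tumours, since library preparation also adds variation. The other closest pairs were tumours 2 and 3 (1.44), 1 and 3 (1.45), 6 and 7 (1.55) and 4 and 5 (1.62), other pairs among tumours 4 to 7 had 2.28 to 4.25, pairs across the sets 7.23 to 12.2, and the closest bone lesions, 7 and 8, 2.03. The orthotopic libraries thus group as 1 to 3, 4 and 5, and 6 and 7, and the labels do not say whether these are 7 separate tumours. Summed to 3 libraries they gave 16 called genes. The alternatives were other size factors, other filters, a replicate block, each library left out, limma-voom with quality weights, mitochondrial and host genes left out, and DESeq2 1.42.0. Other alternatives were added after the composition of the libraries was seen. These were bone lesions under 100000 counts left out, orthotopic tumours 1 to 3 only, orthotopic tumours 4 to 7 only, orthotopic libraries summed to 3, and a covariate for the share of counts in processed pseudogenes. A list or gene was said to reverse only where its value was past the threshold on at least one side of the change.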

Results

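RNA was sequenced from MCF-7 xenografts at different sites of growth, bone lesions after intra-iliac injection (n = 8) and orthotopic tumours of the mammary fat pad (n = 7), and expected counts per human gene were compared between them. The comparison asks how the same breast cancer cells differ in expression between bone and the mammary gland. Total counts were 6601, 169919, 1031804, 1038946, 28547, 330699, 87447 and 68912 in bone lesions 1 to 8. They were 230807, 287012, 250298, 1499869, 760909, 759936 and 340283 in orthotopic tumours 1 to 7. Mean log10 totals were 5.10 ± 0.757 (SD, n = 8) in bone lesions and 5.67 ± 0.310 (SD, n = 7) in orthotopic tumours, which did not differ beyond the spread between libraries (exact permutation test, two-sided p = 0.0867).

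The orthotopic libraries fell into separate sets by composition, tumours 1 to 3 and tumours 4 to 7. Genes that overlap ribosomal RNA genes took 1.17% ± 0.333 (SD, n = 3) of counts in tumours 1 to 3 and 13.1% ± 1.02 (SD, n = 4) in tumours 4 to 7. Processed pseudogenes, copies of spliced messages that are mostly not transcribed, took 2.03% ± 0.25 and 0.354% ± 0.0154 of counts. In bone lesions processed pseudogenes took 2.22% ± 1.04 (SD, n = 8), with 1.01% and 1.19% in bone lesions 3 and 4, the deepest, and 3.91% and 3.48% in bone lesions 7 and 8. The ribosomal share was 49.5% (95% Wilson interval 48.3 to 50.8%) in bone lesion 1 and 35.5% (34.9 to 36.0%) in bone lesion 5, the shallowest libraries. No label gives a batch, and all members of tumours 4 to 7 belong to 1 group, so values against tumours 1 to 3 alone stand beside the pooled ones.

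**Figure D1:**
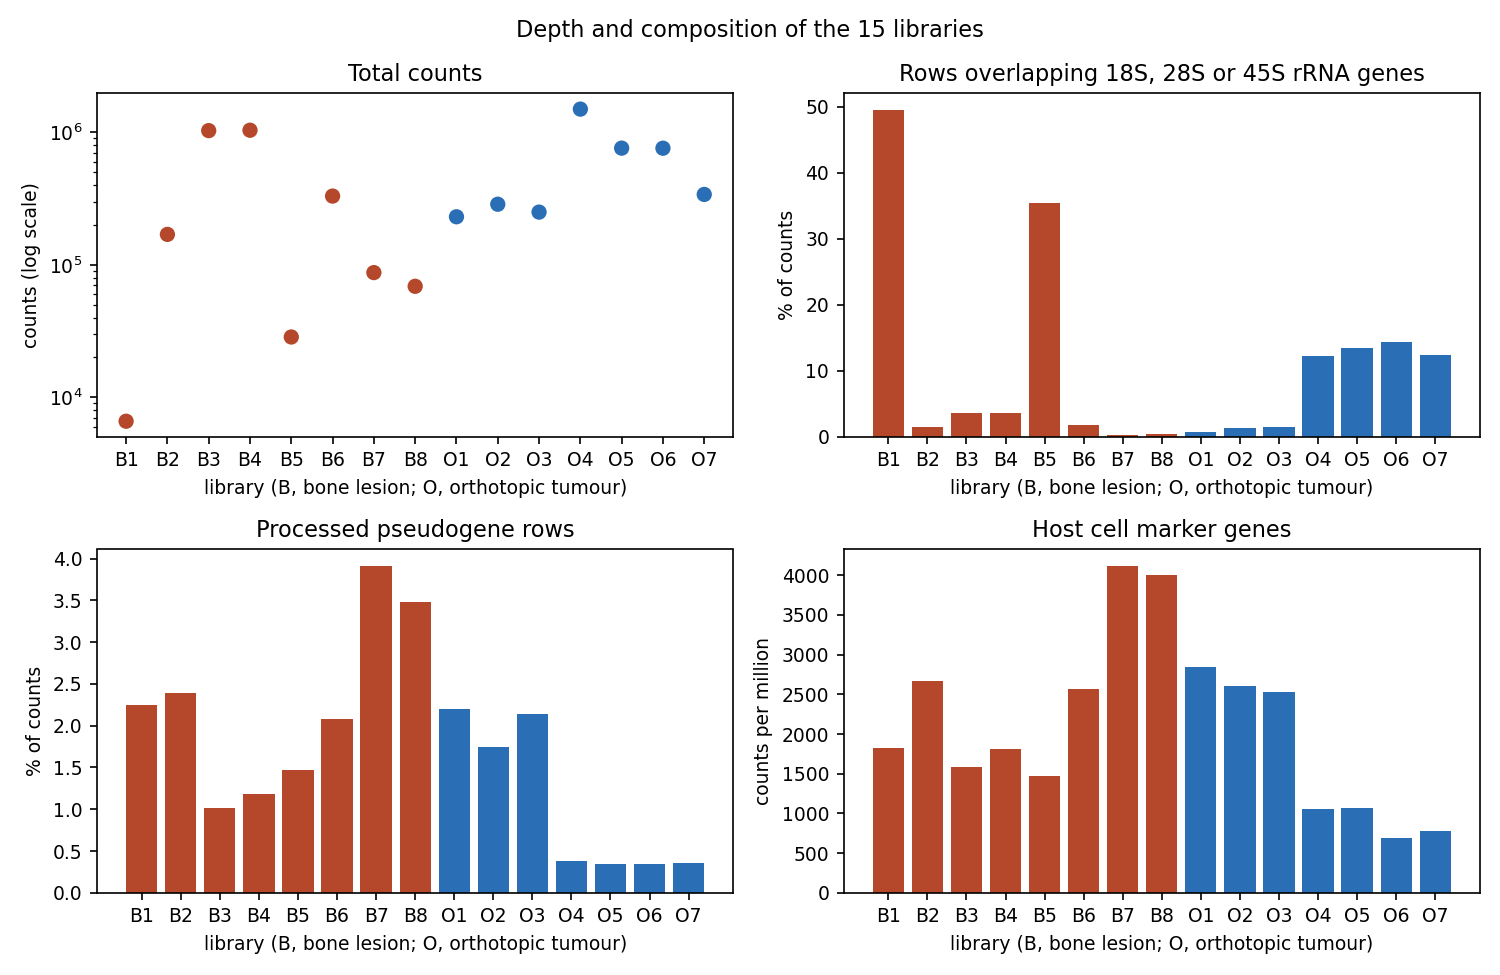
Depth and composition of the 15 libraries (B, bone lesions 1 to 8 in red; O, orthotopic tumours 1 to 7 in blue): total counts on a log axis, percent of counts in genes overlapping ribosomal RNA genes, percent in processed pseudogenes, and CPM of host cell marker genes. Orthotopic tumours 4 to 7 stand apart from tumours 1 to 3 in the last 3 panels, with 897 ± 190 against 2660 ± 167 CPM of host markers.

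Other measures of the libraries did not separate the sites. Mitochondrially encoded mRNAs took 3.59% ± 0.976 (SD, n = 8) of counts in bone lesions and 3.95% ± 1.22 (SD, n = 7) in orthotopic tumours (exact permutation test, two-sided p = 0.529). Bone lesions had 19925 ± 10153 genes with at least 1 count and orthotopic tumours 21142 ± 4461 (exact permutation p = 0.776), and after thinning to the smallest library 3807 ± 855 and 3560 ± 691 (exact permutation p = 0.553). The 100 most abundant genes took 26.9% ± 17.4 and 28.8% ± 11.9 of counts (exact permutation p = 0.815). Without the 4 shallow bone lesions the remaining ones had 27402 ± 3434 genes detected, 6260 more than orthotopic tumours (exact permutation p = 0.0455). None of these measures was past 0.05 against orthotopic tumours 1 to 3 alone, with exact permutation p-values of 0.545 for log10 totals, 0.188 for the mitochondrial share, 0.412 for genes detected and 0.297 for the top 100 genes.

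Over all libraries more genes were called lower than higher in bone lesions, a balance that depended on the libraries and the method. Called lower in bone were 11 of 20 tested genes of the interferon list, the progesterone receptor gene PGR and the collagen genes COL12A1 and COL5A1. ID1, a helix-loop-helix transcription regulator without a DNA-binding domain, was higher. The call of the interferon list was lost with an estimated correlation, and the calls of PGR and COL5A1 were lost against orthotopic tumours 1 to 3. Of 6292 genes tested, 68 passed an adjusted p of 0.05, 6 higher and 62 lower in bone lesions, and 66 of them changed at least 2-fold (6 higher, 60 lower). Folds are those fitted by edgeR, which adds a small prior count and weights libraries by depth, so they differ from ratios of mean CPM. The median log2 fold change of all tested genes was -0.04. It depends on the scaling, since TMM factors computed without the count filter changed the log2 fold changes of these genes by a median of -0.47, so directions close to 0 are open. At an unadjusted p under 0.05 there were 880 genes (328 higher, 552 lower). Comparing bone lesions with orthotopic tumours 1 to 3 alone called 16 genes, 14 of them among the 68, and comparing them with tumours 4 to 7 alone called 1271 (882 higher, 389 lower), including all 68. With limma-voom and quality weights 810 were called (478 higher, 332 lower). With the orthotopic libraries summed to 3 there were 16, all among the 68, 1 higher (ID1) and 15 lower. The calls of ISG15, BST2, ACTG1, HLA-A, PGR, MCM4 and MT-ATP8 were lost there, with larger SEs. Their log2 fold changes were -1.84, -2.12, -2.64, -1.26, -1.53, -1.16 and -1.87. That setting moved the 6292 genes by a median of -0.15, so these values cannot be read as larger falls. Of the 68 genes, 65 had a value against tumours 1 to 3, all 65 in the same direction, 57 of them at an unadjusted p under 0.05. These comparisons share libraries with the one that picked the 68, so a shared direction is largely built in. The count was 30 without orthotopic tumour 4, 31 without orthotopic tumour 5, 37 without bone lesion 2 and 103 without orthotopic tumour 1.

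ID1 rose by a fitted 9.81-fold in bone lesions, with means of 19.6 ± 8.94 CPM (SD, n = 7) in orthotopic tumours and 182 ± 116 CPM (SD, n = 8) in bone lesions. ID1 (ENSG00000125968.8) lies on the plus strand of chromosome 20, from 31605283 to 31606515 in GRCh38, and is known as a direct target of bone morphogenetic protein signalling. Its log2 fold change was 3.29 (SE 0.32, adjusted p = 5.68e-07), and 7 of 8 bone lesions lay above the orthotopic median. The other, bone lesion 1, had a count of 0, which allows up to 250 CPM at its depth. The log2 fold change of ID1 against orthotopic tumours 1 to 3 was 3.40 (SE 0.56, adjusted p = 4.81e-06). Leaving out any 1 of bone lesions 2 to 8 took ID1 below the count filter, so it had no test there. In CPM before TMM scaling, no orthotopic tumour reached the filter's limit of 34.8 for ID1. It was tested only because 7 bone lesions did, so the 7 of 8 follows from the filter and is no separate support.

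The 5 other genes that rose were S100P, SASH1, INAVA, PSD3 and PRCP, which encode a calcium-binding protein, a scaffold protein, an activator of innate immune signalling, an exchange factor for a small GTPase and a lysosomal peptidase. S100P rose by a fitted 2.83-fold, with means of 48.0 ± 14.2 and 126 ± 65.2 CPM (log2 fold change 1.503, SE 0.28, adjusted p = 0.00420), with 7 of 8 bone lesions above the orthotopic median and a count of 0 in bone lesion 1. The log2 fold changes of SASH1, INAVA, PSD3 and PRCP were 1.33, 1.26, 1.17 and 1.02, with adjusted p-values of 0.0440, 0.0327, 0.0322 and 0.0473. The calls of these 5 genes were lost against orthotopic tumours 1 to 3 alone, with values of 1.56 for S100P (adjusted p = 0.245), 1.00 for SASH1, 1.06 for INAVA, 0.93 for PSD3 and 0.57 for PRCP. They were also lost with the orthotopic libraries summed to 3 (values 1.32, 1.23, 1.13, 1.03 and 0.92), a setting that moved all tested genes by a median of -0.15. Leaving out 1 library also ended the calls of SASH1 (bone lesions 2 and 8, orthotopic tumours 2 and 4 to 7, values 1.19 to 1.38), INAVA (bone lesions 2, 3, 4 and 6, orthotopic tumours 4 to 6, values 1.13 to 1.32), PSD3 (bone lesions 4 and 6, orthotopic tumours 4 to 7, values 1.08 to 1.31) and PRCP (bone lesions 1, 2 and 4 to 8, orthotopic tumours 2 and 4 to 7, values 0.92 to 1.10).

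Large falls outside the interferon list included those of PMP22, COL12A1, NPY1R, NECAB1, ACTG1 and LGALS3BP. PMP22, a membrane protein of peripheral myelin and epithelia, fell by a fitted 6.40-fold, with means of 131 ± 21.5 CPM in orthotopic tumours and 18.8 ± 14.97 in bone lesions (log2 fold change -2.68, SE 0.31, adjusted p = 8.10e-06). COL12A1, which encodes a collagen that binds to fibrils, fell 5.59-fold (log2 fold change -2.48, SE 0.38, adjusted p = 0.000490), and COL5A1, a chain of a fibril-forming collagen and a member of the host list of fibroblast markers, had a log2 fold change of -1.73 (adjusted p = 0.00420). NPY1R, a neuropeptide Y receptor, fell by a fitted 4.68-fold, with means of 457 ± 87.2 and 85.8 ± 80.7 CPM (log2 fold change -2.23, SE 0.32, adjusted p = 0.000269). NECAB1, a calcium-binding protein, fell 5.01-fold (log2 fold change -2.32), ACTG1, cytoplasmic gamma actin, 5.28-fold (-2.40), and LGALS3BP, a secreted binding partner of galectin 3, 3.90-fold (-1.96). NPY1R, ACTG1 and LGALS3BP lay below the orthotopic median in 8 of 8 bone lesions, COL12A1 and NECAB1 in 7 and PMP22 and COL5A1 in 6. In the others, bone lesion 1 or bone lesions 1 and 5, a count of 0 allows up to 250 and 156 CPM and cannot be placed. PMP22, COL12A1, NPY1R, NECAB1, ACTG1 and LGALS3BP stayed past the threshold against orthotopic tumours 1 to 3, with log2 fold changes of -2.48, -1.998, -2.10, -2.33, -2.25 and -1.75, while COL5A1 did not (-1.53, adjusted p = 0.0852). ACTG1 has many near-identical copies and its value is uncertain for that reason.

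The noncoding RNAs RN7SK, which holds the elongation factor P-TEFb inactive, and MALAT1, which stays in the nucleus, had large falls over all libraries that were smaller against orthotopic tumours 1 to 3. RN7SK was at 84.1 ± 86.7 CPM in bone lesions and 949 ± 736 CPM in orthotopic tumours (log2 fold change -3.19, SE 0.61, adjusted p = 0.00429). Its log2 fold change against orthotopic tumours 1 to 3 was -0.67, and its call was lost. MALAT1 had a log2 fold change of -2.66 (SE 0.48, adjusted p = 0.00251) over all libraries and -1.54, no longer past the threshold, against tumours 1 to 3. It stood at 3343, 4281 and 3755 CPM in tumours 1 to 3, each above the highest bone lesion, bone lesion 4, at 3058 CPM. Of 8 tested nuclear-retained long noncoding RNAs MALAT1 alone was called, and the list was not (median -0.37, adjusted p = 0.710).

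**Figure D2:**
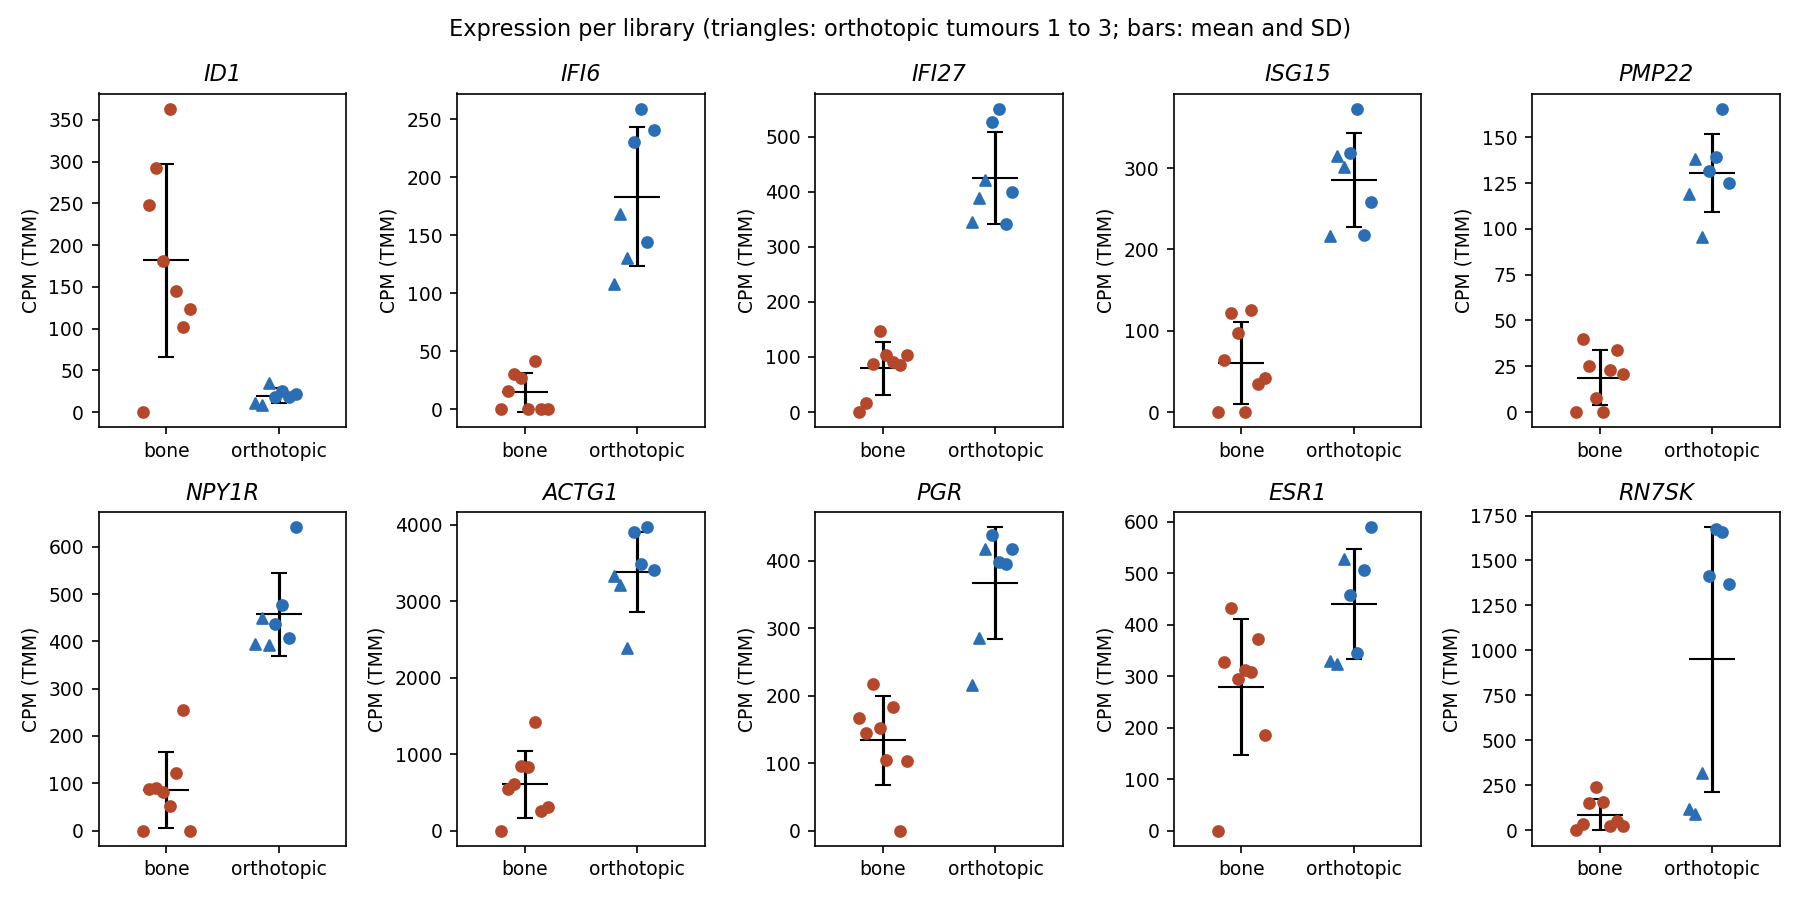
CPM on the TMM scale per library for 10 genes in bone lesions (red, n = 8) and orthotopic tumours (blue, n = 7; triangles, tumours 1 to 3), with mean and SD bars on linear axes. ID1 lay higher in 7 of 8 bone lesions, as the count filter required for its test. IFI27, ISG15, NPY1R, ACTG1 and PGR lay below the orthotopic median in 8 of 8, IFI6 in 7 and PMP22 in 6, with counts of 0 in bone lesions 1 and 5 not placed, while RN7SK was low in tumours 1 to 3 too. ESR1 lay below the orthotopic median in 8 of 8 bone lesions but did not pass the test.

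Most interferon-induced genes tested were lower in bone lesions, though the call of their list was lost with an estimated correlation (adjusted p = 0.962). Of 20 tested members of the interferon list 19 had a log2 fold change below 0, 11 were called lower and 0 higher, and adjusted over the list alone 16 fell and 1 rose. The latter was MX2, an interferon-induced GTPase named after its values were seen, at 1.06 (adjusted p = 0.276 over all genes). The list has 37 members, of which 20 were tested. Members low in bone lesions could pass the filter through the orthotopic tumours alone, so these counts may partly come from the filter. IFI6, an interferon-induced mitochondrial protein, fell by a fitted 7.08-fold, with means of 183 ± 59.9 and 14.3 ± 16.9 CPM (log2 fold change -2.82, SE 0.33, adjusted p = 8.10e-06), and IFI27 by 4.64-fold, with means of 425 ± 83.1 and 79.1 ± 48.2 CPM (-2.22, SE 0.30, adjusted p = 6.94e-05). ISG15, a ubiquitin-like modifier, and IRF9, a subunit of the transcription factor that interferon activates, had log2 fold changes of -1.67 (adjusted p = 0.00103) and -1.77 (adjusted p = 0.00184). BST2, a membrane protein that tethers budding virus, had a log2 fold change of -2.01 (adjusted p = 0.00338), and PARP10, an ADP-ribosyltransferase outside the list, -2.08 (adjusted p = 0.00133). IFI27 and ISG15 lay below the orthotopic median in 8 of 8 bone lesions, IFI6 and IRF9 in 7 and BST2 and PARP10 in 6, the others having counts of 0 that cannot be placed.

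The median log2 fold change of the interferon response list was -1.31 (camera, adjusted p = 3.96e-10). With an estimated correlation the call was lost (adjusted p = 0.962, unadjusted p = 0.0403). Fry gave an adjusted p of 0.0312, but its direction was lower for all 27 lists, so it adds little here. Camera took the same log2 CPM, with shallow libraries weighted like deep ones, so its p-values and directions may also reflect depth. Against orthotopic tumours 1 to 3 the list interferon response had a median of -1.15 (adjusted p = 5.16e-16) with 6 of 21 tested members called lower, among them IFI6 (-2.37), IFI27 (-2.08) and ISG15 (-1.65). Against tumours 4 to 7 its median was -1.26, with 15 of 25 tested members called lower and 2 called higher. Without the shallow bone lesions its median was -1.30, with 12 of 30 tested members called lower. BST2 was not tested against tumours 1 to 3, and IRF9 was not past the threshold there (-1.45, adjusted p = 0.0938).

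Genes of class I antigen presentation, which carry peptides to the cell surface, were lower as a list. HLA-A fell from 143 ± 32.0 to 57.9 ± 34.1 CPM (log2 fold change -1.12, SE 0.26, adjusted p = 0.0244, below the orthotopic median in 7 of 8 bone lesions, with a count of 0 in bone lesion 1 not placed). Of 7 tested members HLA-A alone was called, 4 fell adjusted over the list alone, and the list median was -0.72 (camera, adjusted p = 0.0257; adjusted p = 0.962 with an estimated correlation). Against orthotopic tumours 1 to 3 the median of the list antigen presentation class I was -0.44 (adjusted p = 0.0406) and HLA-A was at -0.99, not past the threshold. Without bone lesion 7 or bone lesion 8 the adjusted p of the list was 0.0507 and 0.0570, and HLA-A was not past the threshold without bone lesion 4 (-1.06) or 6 (-0.98) or orthotopic tumour 4 (-1.08) or 5 (-1.06).

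Oestrogen receptor targets were lower as a list, with PGR the one member that was called. PGR (ENSG00000082175.14, chromosome 11, 101029624 to 101130524) fell by a fitted 2.47-fold, with means of 367 ± 83.0 CPM (SD, n = 7) and 134 ± 66.0 CPM (SD, n = 8). Its log2 fold change was -1.31 (SE 0.30, adjusted p = 0.0244). Its values lay below the orthotopic median in 8 of 8 bone lesions, though those of bone lesions 1 and 5 rest on 2 counts each. ESR1, the oestrogen receptor gene itself, was at 279 ± 133 and 440 ± 108 CPM in bone lesions and orthotopic tumours, a log2 fold change of -0.51 that was not past the threshold (SE 0.28, adjusted p = 0.414). ESR1 lay below the orthotopic median in 8 of 8 bone lesions and was past the threshold in 0 of 27 alternatives (-1.04 to -0.31). An unchanged level of ESR1 is thus not shown. GREB1, a cofactor induced by oestrogen, was at -0.87 (SE 0.46, adjusted p = 0.399). Of 32 tested members of the list 1 fell and 0 rose, and 8 fell adjusted over the list alone. The list median was -0.46 (camera, adjusted p = 0.0256; adjusted p = 0.962 with an estimated correlation).

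Both calls depended on the libraries compared. Against orthotopic tumours 1 to 3 the median of the list estrogen receptor target genes was -0.21 (adjusted p = 0.113), PGR was at -1.05, no longer past the threshold, and GREB1 was at 0.17. Without the shallow bone lesions the list median was -0.21 (adjusted p = 0.0847), and without bone lesion 7 or bone lesion 8 alone the adjusted p was 0.0678 and 0.0570. PGR was not past the threshold without bone lesion 2 (-1.29) or without orthotopic tumour 4 (-1.26), 5 (-1.30) or 7 (-1.28).

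The luminal transcription factor genes GATA3 and FOXA1 had log2 fold changes of -1.16 (SE 0.34, adjusted p = 0.108) and -0.54 (SE 0.32, adjusted p = 0.460). They lay below the orthotopic median in 8 and 6 of 8 bone lesions. GATA3 was past the threshold without bone lesion 1 (-1.06, adjusted p = 0.0409) and with DESeq2 (-1.09, adjusted p = 0.00330). Of 19 tested luminal genes 0 were called by edgeR, 1 fell adjusted over the list alone, and the list was not called (median -0.32, adjusted p = 0.115). Basal epithelial genes (6 tested, median -0.22) and genes of the epithelial-mesenchymal transition (6 tested, median 0.06) had 0 members called, and their adjusted p-values were 0.530 and 0.865. Cell junction genes had a median of -0.24 over 12 members (adjusted p = 0.115), and CDH1, the E-cadherin gene, was at -0.10 (adjusted p = 0.937).

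Signalling lists had few or no called members. Receptor tyrosine kinase genes had a median of -0.57 over 10 tested members, 0 called and 4 lower adjusted over the list alone (camera, adjusted p = 0.115), with IGF1R at -1.05 (adjusted p = 0.151). The list receptor tyrosine kinases was called without bone lesion 1 (median -0.56, adjusted p = 0.0349). FGFR1 lay below the count filter, at 32.2 ± 20.6 CPM in bone lesions and 40.8 ± 8.99 CPM in orthotopic tumours. Calcium signalling genes (23 tested, median -0.08, adjusted p = 0.874) and mTOR pathway genes (21 tested, median -0.13, adjusted p = 0.530) had 0 members called. The gap junction gene GJA1 and the calcium-dependent factors NFATC1 and MEF2C also lay below the filter. Their levels were 12.997 ± 17.6, 35.3 ± 49.3 and 23.2 ± 30.6 CPM in bone lesions and 5.45 ± 7.30, 21.8 ± 9.85 and 15.5 ± 20.3 CPM in orthotopic tumours, from 11 to 57 counts over each group. Without a filter FGFR1, GJA1, NFATC1 and MEF2C had log2 fold changes of -0.48, 0.99, -0.09 and 0.76, with adjusted p-values of 0.489, 0.489, 0.966 and 0.489. These values hold the shift of that setting, a median of -0.47 over the 6292 genes. Of 11 tested TGF-beta and BMP response genes ID1 alone was called (median 0.11, adjusted p = 0.483), and BMP7, a BMP ligand gene, was at 1.16 (SE 0.30, adjusted p = 0.0551), from 418 ± 120 CPM in orthotopic tumours to 897 ± 338 CPM in bone lesions. BMP7 was past the threshold with DESeq2 (1.24, adjusted p = 1.42e-05) and without bone lesion 1 (1.25), 4 (1.24) or 7 (1.21), and was at 0.76, not past it, against tumours 1 to 3. The Wnt response list had a median of -0.30 over 5 members (adjusted p = 0.865).

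Chromatin and growth lists were not called either. EZH2, the methyltransferase of Polycomb repressive complex 2, was at 112 ± 58.9 CPM in bone lesions and 102 ± 24.8 CPM in orthotopic tumours (log2 fold change 0.22, SE 0.24, adjusted p = 0.709), and the 11 tested genes of the complex had a median of -0.14 (adjusted p = 0.483). MKI67, a proliferation marker, was at -0.57 (SE 0.32, adjusted p = 0.428). Of 28 tested proliferation genes 1 was called, MCM4, a subunit of the replicative helicase, which fell 2.02-fold (log2 fold change -1.02, SE 0.22, adjusted p = 0.0162, below the orthotopic median in 7 of 8 bone lesions, with a count of 0 in bone lesion 1 not placed) and was not past the threshold against orthotopic tumours 1 to 3 (-1.05) or without orthotopic tumour 5 (-0.99). The proliferation list had a median of 0.15 and a camera direction of lower (adjusted p = 0.732). Stem and progenitor genes had a median of 0.31 over 5 members (adjusted p = 0.817), hypoxia genes 0.30 over 13 (adjusted p = 0.732) and glycolysis genes 0.01 over 13 (adjusted p = 0.874).

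Genes of the small ribosomal subunit were higher as a list by a small amount that turned to -0.35 without the count filter, with 0 of 30 tested members called by edgeR and 0 adjusted over the list alone. The list median was 0.26 (camera, adjusted p = 0.0481; adjusted p = 0.962 with an estimated correlation), and 26 of 30 members had a fold change above 0. RPS3 had a log2 fold change of 0.54 (SE 0.40, adjusted p = 0.549). For the list small ribosomal subunit proteins the median was 0.50 (adjusted p = 2.90e-07) against orthotopic tumours 1 to 3 and 0.03 (adjusted p = 0.871) against tumours 4 to 7. Without bone lesion 8 its adjusted p was 0.244, and without orthotopic tumour 1, 2 or 3 it was 0.248, 0.243 and 0.241. The call was also lost without bone lesion 5 (adjusted p = 0.124) and without bone lesion 7 (adjusted p = 0.0507). Limma-voom with quality weights, orthotopic libraries summed to 3 and the replicate block each called 0 lists higher, so the call was lost there too. The small subunit list was past the threshold, in either direction, in 14 of 30 alternatives, and reversed in 4. The list large ribosomal subunit proteins had a median of 0.20 over 44 members (adjusted p = 0.115) and was called without bone lesion 1, 3, 4 or 6 or orthotopic tumour 6, with medians of 0.30, 0.25, 0.35, 0.29 and 0.30.

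Other lists of cell processes were not called. The medians were 0.14 for nuclear genes of oxidative phosphorylation, -0.05 for cholesterol synthesis, -0.24 for the unfolded protein response, -0.04 for immediate early genes, -0.09 for heat shock proteins and -0.14 for apoptosis and p53 response genes, with adjusted p-values of 0.732, 0.874, 0.483, 0.530, 0.483 and 0.420. Mitochondrially encoded mRNAs had a median of -0.34 (adjusted p = 0.865), and of them MT-ATP8, which overlaps MT-ATP6, was called (log2 fold change -1.64, adjusted p = 0.0390). The call of MT-ATP8 was lost with DESeq2, without any 1 of bone lesions 2 to 6 or 8 or orthotopic tumours 4 to 7 (values -1.71 to -1.38), and against tumours 1 to 3 (-0.33). Median, mean and camera direction did not share a sign in 7 lists, among them the Wnt and mitochondrial lists, whose median and mean were negative and whose camera direction was higher. Camera weighted all libraries alike, shallow ones included, while the fitted fold changes weight them by depth. Genes of bone metastasis and osteomimicry (4 tested), the Notch response (2), neural markers (1) and replication-dependent histones (3) had too few tested members for a list test, and 0 of them were called by edgeR.

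**Figure D3:**
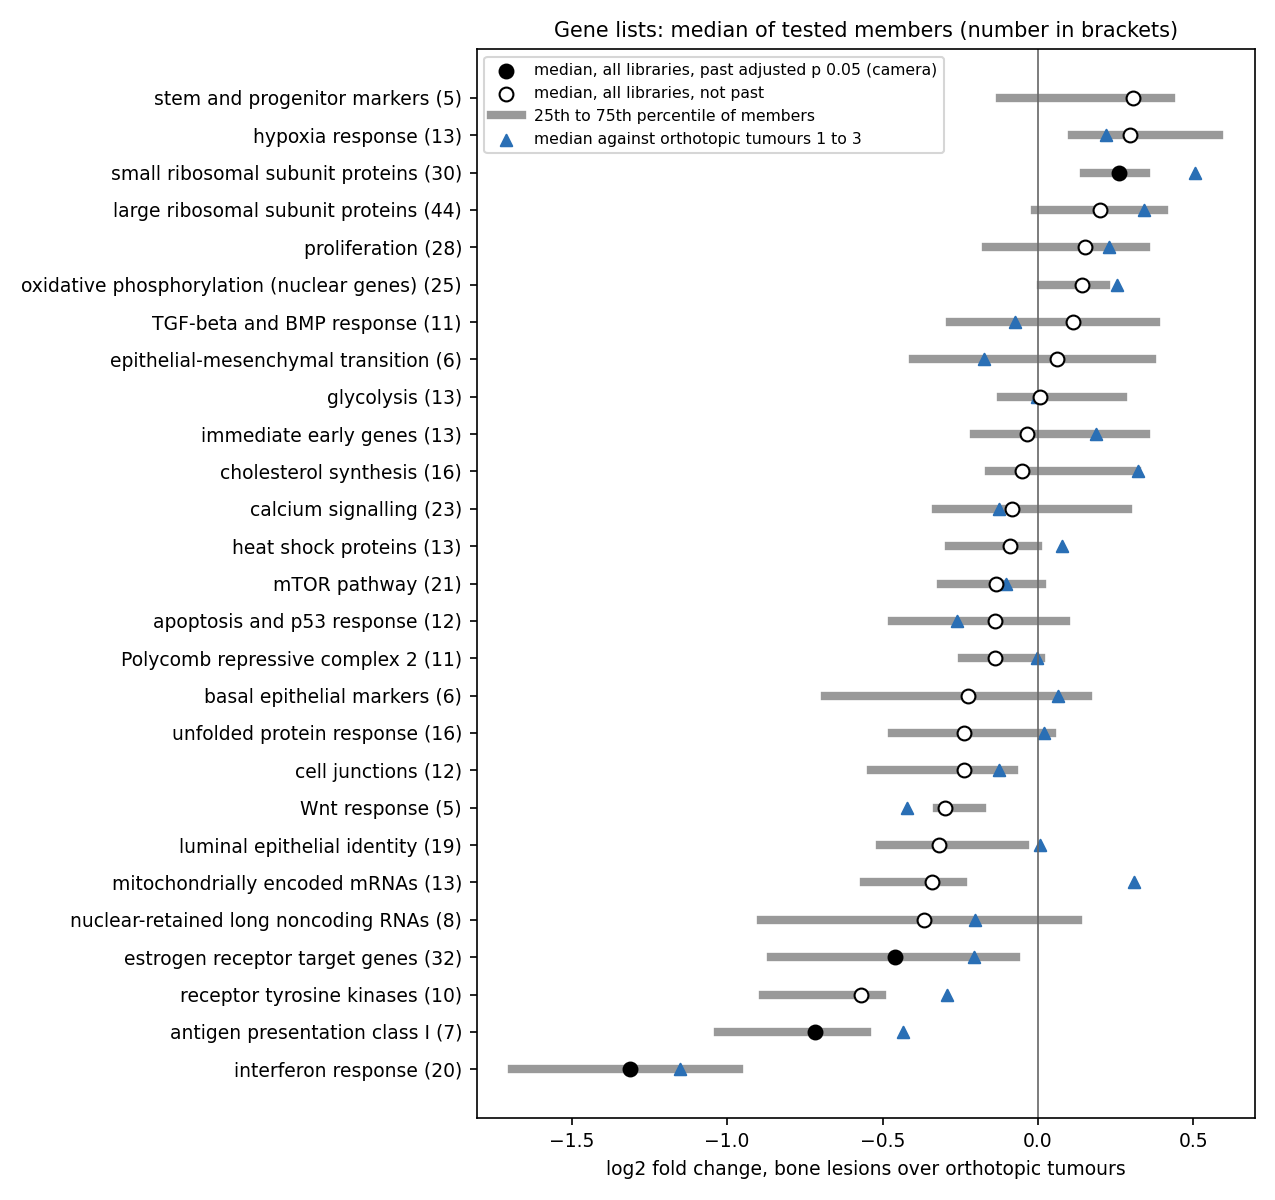
Median log2 fold change, bone lesion over orthotopic tumour, of the tested members of 27 gene lists (circles, filled where camera was past an adjusted p of 0.05; bars, 25th to 75th percentile of members; triangles, medians against orthotopic tumours 1 to 3, drawn for lists with at least 5 members tested there). The interferon response list lay lowest, at -1.31, and at -1.15 against orthotopic tumours 1 to 3.

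Markers of host cells gave few counts on human genes, and their level followed the orthotopic sets. Over all 13 host lists together bone lesions had 2507 ± 1052 CPM (SD, n = 8) and orthotopic tumours 1653 ± 956 CPM (SD, n = 7), which did not differ beyond the spread (exact permutation test, two-sided p = 0.128). Tumours 1 to 3 had 2660 ± 167 CPM and tumours 4 to 7 had 897 ± 190 CPM. Host markers also differed among bone lesions, at 4118 and 4007 CPM in bone lesions 7 and 8 and 1586 and 1816 CPM in bone lesions 3 and 4. Processed pseudogenes took 3.91, 3.48, 1.01 and 1.19% of counts in these libraries. Bone lesion 1, with 12 host marker counts, stood at 1820 CPM and 2.24%. A link between the measures was not tested. The difference of bone lesions was -153 CPM against tumours 1 to 3 (exact permutation p = 0.909) and 1609 CPM against tumours 4 to 7 (exact permutation p = 0.0182).

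Of the 13 host lists alone, macrophage and osteoclast markers (160 and 52.2 CPM in bone lesions and orthotopic tumours), cartilage markers (152 and 80.03 CPM) and adipocyte markers (209 and 97.2 CPM) had the smallest p-values. Exact permutation p-values were 0.0134, 0.00808 and 0.0474, and 0.0869, 0.0869 and 0.205 adjusted over the 13 lists. These differences followed the orthotopic sets, with pooled log2 ratios of 1.34, 0.88 and 1.34 over all tumours, -0.21, 0.11 and -0.64 against tumours 1 to 3, and 2.18, 1.14 and 2.94 against tumours 4 to 7. The other 10 lists, namely erythroid, neutrophil, lymphocyte, megakaryocyte, osteoblast, fibroblast, endothelial, skeletal muscle, smooth muscle and milk-secreting epithelial markers, had exact permutation p-values from 0.0901 to 0.887. Of the 3 fibroblast markers tested as genes COL5A1 alone was called, and it was lower. PECAM1, an endothelial adhesion gene, was at 299 ± 204 and 123 ± 149 CPM on the TMM scale (log2 fold change 1.42, SE 0.72, adjusted p = 0.388). The pooled log2 ratio of endothelial markers was 1.37 over all orthotopic tumours, -0.77 against tumours 1 to 3 and 3.52 against tumours 4 to 7.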

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

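The values below were found by a test for a sample that stands apart from its group, applied to 68 groups of values, and 5 stood apart. Chance alone gives about 1 in 20 groups.

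GJA1 stood at 50.8 CPM in bone lesion 7, from 3 counts, against a next highest value of 24.0 CPM. In orthotopic tumour 1 GJA1 stood at 21.6 CPM, from 4 counts, against 4.32 CPM in the next. NFATC1 stood at 156 CPM in bone lesion 5, from 3 counts, against 25.6 CPM. INAVA, one of the 6 genes that rose, stood at 208 CPM in the same shallow library, from 4 counts, against 110 CPM. NPY1R stood at 642 CPM in orthotopic tumour 7, from 149 counts, against 478 CPM in the next.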

How the results depend on the processing

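Alternatives that left out shallow bone lesions, split or summed the orthotopic libraries or added a covariate were chosen after seeing the data. DESeq2 (68 genes, 56 shared with edgeR), other size factors (63, 59 shared), a stricter filter (49, 36 shared), mitochondrial and host genes left out (66, 64 shared), shallow bone lesions left out (77, 48 shared) and the covariate (62, 38 shared) gave counts of called genes within 1.5 times 68. ID1 stayed past the threshold in all 19 alternatives that tested it (log2 fold change 2.82 to 3.79, adjusted p 1.73e-16 to 0.00114). IFI6, PMP22, COL12A1, NECAB1, NPY1R, IFI27, PARP10 and LGALS3BP did so in 27 of 27. In the alternatives without a value for ID1, too few bone lesions reached the filter's limit. The list interferon response kept its call in 28 of 30 (median -1.67 to -1.15), and lost it wherever the correlation between genes was estimated. PGR kept its call in 18 of 27 (-1.79 to -0.97) and PRCP in 6 of 27. Depth limits what could be tested, since 6292 of 58037 genes passed the filter.

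The count of called genes moved to 122 without a filter, 810 with limma-voom and quality weights (478 higher and 332 lower, 579 at least 2-fold), 16 against orthotopic tumours 1 to 3, 1271 against tumours 4 to 7 (882 higher and 389 lower, 1118 at least 2-fold) and 16 with orthotopic libraries summed to 3. The cause was not tested. Leaving out each library gave 30 to 103 genes, 30 to 101 at least 2-fold and 1 (without bone lesion 7 or 8) to 6 lists. Called lists numbered 24 without a filter, 14 with the stricter one, 0 with an estimated correlation, 1 with fry, 0 with an estimated correlation and shallow bone lesions left out, and 2 against tumours 4 to 7.

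With the replicate number as a block 168 genes were called, 107 higher and 61 lower, 50 of them shared, and 2 lists. Same-numbered samples correlated over 0.1 in 2 of 7 pairs and 0 were best matched to their own number, so no pairing by number was seen. Depth and composition differ between libraries of the same group and could hide a shared animal. Whether same-numbered samples belong together therefore stays open. No measure per library changed its side of 0.05 under the block.

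The filter sets the genes that TMM uses: without it the 6292 genes shifted by a median of -0.47 on the log2 scale, and with the stricter filter by -0.25. List medians turned without a filter to -0.35 for oxidative phosphorylation, -0.31 for TGF-beta and BMP response, -0.34 for large and -0.35 for small ribosomal proteins. Cholesterol synthesis, at -0.31, and mitochondrially encoded mRNAs, at -0.98, had negative medians before and turned in camera direction to lower. These moves hold that shift, and the rest of their cause was not tested. Small ribosomal proteins were at -0.10 with the stricter filter, lower by fry at a median of 0.26, and at 0.0250 against tumours 4 to 7. Mitochondrially encoded mRNAs were at -0.59 and lower with limma-voom, and glycolysis was at 0.39 and higher without shallow bone lesions; the cause of these last moves was not tested.

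Genes detected were higher by 6260 without shallow bone lesions, which by construction takes out the least deep libraries. Host marker differences passed an unadjusted exact permutation threshold for macrophage (108 CPM), adipocyte (112 CPM) and cartilage markers (72.4 CPM) alone and against tumours 4 to 7 (1609 CPM). Leaving out each library gave differences of -0.70 to -0.38 in log10 totals (past 0.05 without bone lesion 3 or 4), -0.616 to -0.0978 in mitochondrial percent, -2741 to 1309 genes detected, -6.72 to 0.398 in percent of the top 100 genes and 624 to 1053 CPM of host markers.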

Other observations

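The tests against orthotopic tumours 1 to 3 and without shallow bone lesions, the splits of bone lesions and tumours 1 to 3, the bound on endothelial markers over tumours 1 to 3, the rule that voids a host marker test where the ratio follows the orthotopic sets, and the test of RN7SK were chosen after the composition of the libraries or the result was seen.

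With the 4 shallow bone lesions left out, hypoxia genes and glycolysis genes, which serve growth at low oxygen, had positive medians, with calls that depended on the method. The list hypoxia response had a median log2 fold change of 0.46 over 16 tested members (camera, adjusted p = 0.00509), and the list glycolysis 0.39 over 16 (adjusted p = 0.00626). Neither was called with an estimated correlation there (adjusted p = 0.747 for both). Over all libraries neither was called, with medians of 0.30 and 0.01. Against orthotopic tumours 1 to 3 one of the 3 genes called higher was RN7SL1, the RNA of the signal recognition particle, at a log2 fold change of 5.21 (SE 0.78, adjusted p = 2.45e-07). RN7SL1 was chosen after its values were seen and was not called over all libraries.

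Whether the groups themselves give the counts of calls was asked with 100 splits of the 15 libraries into 8 and 7, the real one included. For the 68 called genes 2 of 100 splits gave as many, and for the 66 genes of at least 2-fold also 2 of 100, which is under 0.05. Most splits broke up orthotopic tumours 4 to 7, and of the 8 other splits that kept them together 1 gave as many in both cases, so against such splits chance is not excluded. The highest other split gave 297 genes, 279 of them at least 2-fold. It placed orthotopic tumours 3 to 7 with bone lesions 1, 3 and 5, which points to a structure of the samples other than the sites, while the other 7 that kept tumours 4 to 7 together gave 0 to 2 genes. For the 16 genes called against tumours 1 to 3, 9 of 100 splits of these 11 libraries gave as many, with a highest of 644, so chance cannot be excluded for that count, and the bone lesions hold structure of their own. For the 4 called lists 24 of 100 splits gave as many, with a highest of 7, so chance cannot be excluded for the number of lists. Of the 8 other splits that kept tumours 4 to 7 together 0 gave as many lists.

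The lower interferon genes in bone lesions stood out in size and in number, though the filter favours members high in orthotopic tumours, so the number may partly come from it. The composition of orthotopic tumours 4 to 7 is argued against as the whole cause by the median of -1.15 (95% bootstrap interval over list members -1.57 to -0.81) against tumours 1 to 3, and the shallow bone lesions by the median of -1.30 (-1.52 to -0.95) without them. The bootstrap drew list members, which vary together, and not libraries. These intervals therefore do not measure the spread between libraries. A lower share of mouse cells in bone lesions stays open: macrophage, fibroblast and endothelial markers had pooled log2 ratios of 1.34, 0.57 and 1.37 (second highest of their lowest values with a library left out, 0.850), but -0.21, 0.09 and -0.77 against tumours 1 to 3 and 2.18, 0.70 and 3.52 against tumours 4 to 7. All 13 host lists moved this way, so the markers follow the orthotopic libraries and cannot be read as a share of mouse cells, and how mouse reads were set apart is not given in the sources used here. The interferon median did not move with the markers, at -1.15 against tumours 1 to 3 and -1.26 against tumours 4 to 7. The site itself was not tested apart from these explanations, and the list was not called with an estimated correlation, so coordinated variation between single tumours also stays open.

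ID1 was the gene with the smallest adjusted p. The composition of tumours 4 to 7 is argued against by a log2 fold change of 3.40 (interval 2.28 to 4.52) against tumours 1 to 3, and the shallow bone lesions by 3.42 (2.88 to 3.96) without them. Mouse endothelial cells, which express Id1, stay open, since endothelial markers were at -0.77 (-0.88 to -0.52 with each library left out) against tumours 1 to 3, 3.52 against tumours 4 to 7 and 1.37 over all, and so follow the orthotopic libraries, while ID1 did not follow them (8.64 to 35.2 CPM in tumours 1 to 3, 17.96 to 25.1 CPM in tumours 4 to 7), which argues against these marker reads as its source but leaves a small share of such cells hidden by their baseline. A BMP response of the tumour cells may be the source, with BMP7 at 1.16 (adjusted p = 0.0551), but of 7 other SMAD targets SMAD6 alone was tested, at 1.02. Without a filter ID2, ID3 and ID4 were at 1.56, 0.78 and 2.67, ATOH8 and SMAD6 at 0.81 and 0.57, SMAD7 and BAMBI at -0.67 and -0.89. That setting moved the 6292 genes by a median of -0.47, so these values are not on the scale of ID1 and BMP7 above. None of the targets passed an adjusted p, so a BMP response stays open.

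RN7SK had the largest fall among the named genes over all libraries. Its log2 fold change of -0.67 (interval -1.45 to 0.11) against tumours 1 to 3 is consistent with the library composition of tumours 4 to 7 as a candidate cause. Because no bone lesion shares that composition, a difference between the sites cannot be set apart from it for this gene in tumours 4 to 7.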
